A study of Mus musculus with 5 samples.

How the data were processed

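RNA was measured in atrial tissue of mice at postnatal day 1. Per the labels' protocols, tissue was dissolved in Trizol and RNA was purified on RNeasy columns. Libraries were then made from 250 ng of total RNA with Illumina's TruSeq RNA kit, and the labels give the molecule as polyA RNA. There were 5 libraries, 3 of control atria (replicates 2, 4 and 6) and 2 of mutant atria (replicates 5 and 7). The groups share no replicate number, so no pairing was used.

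The authors deposited raw read counts per gene and library in 1 table of 40624 genes, and per the file headers the columns are named by group letter and replicate. Per the submitters' processing notes, the genome build was mm9 and the tools included TopHat2 2.0.4, HTSeq 0.5.4p3 and DESeq; the notes used here give no role for each. Whether counting used strand is not given in the sources used here. Reads of a gene and of a gene on the opposite strand of the same exons could therefore not be told apart. By the reference described below, exonic bases are shared in this way by Smyd2 (814), Ctgf (665), Lnx1 (466), Hopx (412) and other genes named in the text. The same table holds RPKM values, which the authors pooled to 1 value per group, and the authors' log2 ratio of mutant over control. It also holds the authors' deposited p-value and adjusted p-value for each gene. A shorter deposited table of 1342 genes holds the genes whose p-value lay under 0.01 and whose larger RPKM lay above 1, a rule tested on its values. The no_feature and ambiguous entries of the counting tool stand in the full table as if they were genes, and the authors' deposited adjusted p for the ambiguous entry was 0.0302. These entries were left out of library totals and tests here. The no_feature share was 4.26%, 4.70% and 6.03% of all counts in controls 2, 4 and 6, and 3.97% and 5.75% in mutants 5 and 7. The ambiguous share was 3.09%, 3.18% and 2.87% in the controls and 2.45% and 2.31% in the mutants.

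Coordinates are those of the deposited table (mm9). For protein-coding genes its listed start and end have the length of the coding span, not of the gene: of 19736 genes compared by identifier with GENCODE vM21, 90.7% had the coding length within 3 bases. That reference is built on GRCm38, so it served only for names, coding lengths and the question of which genes share exonic bases, and no coordinate of it is printed. Among the deposited gene symbols, 25 stand as 5-digit numbers, and 24 of these genes are named Sept or March in the reference; 22 were tested, under their Ensembl identifiers.

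The counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults (a minimum count of 10 and a minimum total of 15), which left 17835 genes. Library totals were scaled by TMM. Each gene was tested with edgeR's quasi-likelihood test (robust fit, two-sided, no covariate), and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Fold changes are mutant over control on the log2 scale, with a prior count of 0.125, and the standard error is the fold change divided by the square root of the F statistic. Levels are CPM, the counts divided by the TMM-scaled library totals and put on a common scale by edgeR. With 2 against 3 libraries an exact two-sided permutation test of a single gene cannot go below p = 0.1, so significance rests on the model that shares information between genes.

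The 28 gene lists were fixed before the data were examined, and so were the main test and the rule for named genes. Lists were tested with camera (limma 3.58.1) on log2 CPM with a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 28 lists. With an estimated correlation camera takes its degrees of freedom from the libraries, which are few here. No list passed that way (smallest camera adjusted p = 0.287), so a call lost there says little on its own. Fry asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. Its mixed version asks whether they change in either direction. Values of fry are those for 1 direction unless the mixed version is named. Members are counted at adjusted p under 0.05 over all tested genes and again adjusted over the list alone. Named genes are Nkx2-5; Sln, Hcn4, Tbx3, Notch1, Jag1, Nppa, Gja5, Myl7 and Myl2 whatever their result; the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 1 and non-overlapping groups, leaving out sex-linked genes and genes without a symbol; and up to 4 members of each list with the smallest p. Not every gene that this rule names is given in the text.

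Alternatives fixed in advance were DESeq2's size factors within edgeR, library totals alone, no filter, a filter of at least 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, a threshold of 0.01, leaving out each library, sex as a covariate, and leaving out the erythroid genes. Thinning all libraries to the smallest total, a sex by genotype interaction and the enrichment of annotation terms were added after the data had been seen. Term enrichment used the function terms of the deposited table, with a one-sided hypergeometric test in SciPy 1.17.1 over terms of 10 to 500 tested genes. Figures were drawn with matplotlib 3.10.9.

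The functions were tested on simulated counts drawn from the means, library totals and dispersions of these libraries, with 200 of the tested genes changed. For this comparison edgeR recovered 34.3% of 67 genes changed 1.5-fold, 67.2% of 67 changed 2-fold and 89.4% of 66 changed 4-fold, all in the right direction. Of its 148 calls in that simulation, 21 were genes left unchanged, which is more than the threshold of 0.05 allows. DESeq2 called 178 genes there, 43 of them unchanged. A simulated list of 30 genes raised 1.5-fold was found by camera, and 2 of 100 unchanged lists passed an unadjusted p of 0.05, against 12 of 100 with fry. No column of per-sample values was left unused.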

Results

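Nkx2-5 is a homeodomain transcription factor of the developing heart. The study removed it from atrial muscle with a Cre recombinase expressed from Sln, the gene of sarcolipin, a small calcium pump inhibitor of atrial myocytes. Gene expression was compared in atria of newborn mice. Control atria carried the Cre and 1 floxed Nkx2-5 allele, and mutant atria carried the Cre with both alleles floxed, so the groups differed in the second allele and not in the Cre. The 5 libraries held 58.5, 58.9 and 60.9 M gene counts in controls 2, 4 and 6, and 78.8 and 69.6 M in mutants 5 and 7. Across genes, Spearman's rho between libraries was 0.992 to 0.994 within a group and 0.987 to 0.990 between groups. Replicates differed by more than sampling noise, with a chi-square of 20.3 to 85.4 per degree of freedom, so no library was a copy of another. The labels do not state whether the libraries came from separate animals, so p-values measure the spread between these samples.

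The first question was whether the labels match the level of the targeted gene. Nkx2-5 (ENSMUSG00000015579; coding span on chromosome 17, 26975967 to 26978300, mm9) stood at 76.8, 72.1 and 71.3 CPM in controls 2, 4 and 6 and at 5.79 and 5.21 CPM in mutants 5 and 7. It fell by 3.74 ± 0.09 (SE) on the log2 scale, to a mean of 5.50 ± 0.41 CPM (SD, n = 2) from 73.4 ± 2.95 CPM (SD, n = 3). The adjusted p was 7.0e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Sln itself, whose promoter drives the Cre, had a log2 fold change of -0.17 ± 0.07 (SE) and did not pass (adjusted p = 0.25 by the same edgeR test).

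Sex was read from the X-inactivation RNA Xist and the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty. Control 4 and mutant 5 had 4739 and 5870 counts of Ddx3y and 67 and 107 counts of Xist. Controls 2 and 6 and mutant 7 had 27872, 37463 and 68165 counts of Xist and at most 3 of Ddx3y. Each group therefore held libraries of both sexes, with 1 male library in each. None of the 5 sex-linked genes passed edgeR's test between the groups, 0 of the 5 reached an unadjusted p under 0.05, and limma-voom called 0. The list did not pass camera (median 0.48, adjusted p = 0.71, and 0.83 with an estimated correlation). Its median turned to -0.08 without control 2 or control 6.

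Genes changed in both directions in mutant atria. Tnnt3, which encodes the troponin T of fast skeletal muscle, stood at 58.7, 88.6 and 32.7 CPM in controls 2, 4 and 6 and rose to 1052 ± 45.9 CPM (SD, n = 2). The lipoxygenase gene Alox8 rose 9.57-fold from 23.9 ± 2.66 CPM (SD, n = 3). Hey2, a transcriptional repressor best known from the compact ventricular wall, rose 6.04-fold, and the lysine methyltransferase gene Smyd2 rose 4.85-fold. In the other direction, Nppa, the precursor of atrial natriuretic peptide, fell from 6086 ± 751 CPM (SD, n = 3) to 1021 ± 244 CPM (SD, n = 2). In all, 1174 of 17835 tested genes passed adjusted p under 0.05 in edgeR's quasi-likelihood test, 538 higher and 636 lower in mutant atria. Of these, 125 were higher and 183 lower by 2-fold or more, and 1142 were protein-coding. All 1174 had mutant values wholly above or below the control values, as did 37.9% of all tested genes, against 20% by chance. The number of calls depended on single libraries. It was 223 higher and 306 lower without control 2, 203 and 331 without control 4, 327 and 419 without control 6, and 910 and 804 without mutant 5. It was also 924 higher and 1032 lower with DESeq2, and 470 and 514 with sex as a covariate.

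**Figure D1:**
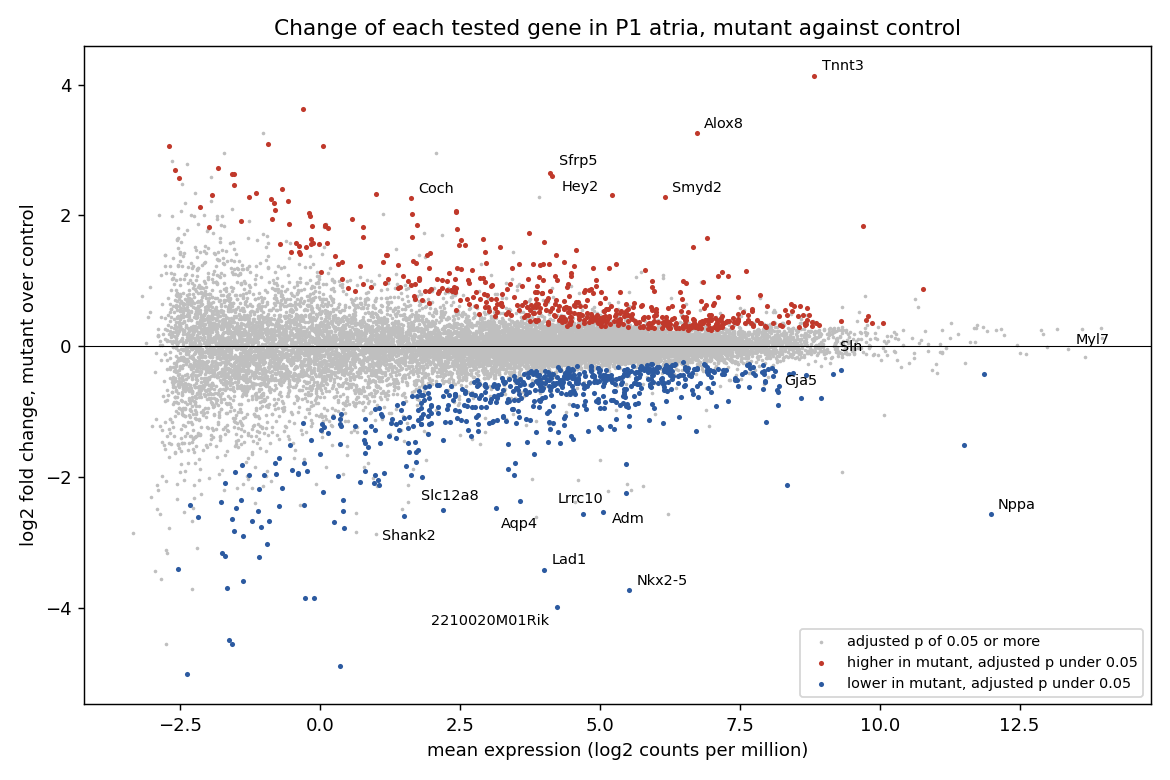
Each point is 1 of the 17835 tested genes, with mean expression in log2 CPM on the x axis and the log2 fold change of mutant over control on the y axis; red points passed as higher (538) and blue points as lower (636) at adjusted p under 0.05 in edgeR's quasi-likelihood test. Tnnt3 lies highest among the labelled genes and 2210020M01Rik and Nkx2-5 lie lowest.

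Among the 10 largest rises, the secreted Wnt antagonist Sfrp5 rose by 2.65 ± 0.33 (SE) on the log2 scale, the defensin gene Defb19 by 2.02 ± 0.23, the extracellular matrix gene Coch by 2.26 ± 0.45, the estrogen receptor gene Esr1 by 2.06 ± 0.29 and the ubiquitin ligase gene Lnx1 by 2.05 ± 0.40. BC048546 rose by 2.31 ± 0.22, but it lies beside the related gene Pzp, and whether the 2 share reads was not tested, which leaves its value uncertain. Tnnt3 rose by 4.13 ± 0.50, with an adjusted p of 0.032 by edgeR's test with Benjamini-Hochberg adjustment. It did not pass when no filter on low counts was used. Several of these calls were lost when 1 library was left out, at folds close to those above. Tnnt3 lost its call without control 2, mutant 5 or mutant 7 (highest adjusted p = 0.18, edgeR). Coch lost it without control 2, mutant 5 or mutant 7 (highest 0.19), and Lnx1 without control 2, control 4, mutant 5 or mutant 7 (highest 0.19). Sfrp5 lost it without control 2 or control 6 (highest 0.073), and Esr1 without control 2 or mutant 7 (highest 0.054). The log2 fold change of Tnnt3 was at least 3.84 whichever library was left out. Control 6 stood well below controls 2 and 4 for Tnnt3, Esr1, Lnx1 and Coch. Lnx1, for example, stood at 1.14 CPM in control 6 and at 2.99 and 3.01 CPM in controls 2 and 4. This was not so for Alox8, Sfrp5, Hey2, BC048546, Smyd2 or Defb19, and its cause was not tested. Defb19, Alox8, Hey2, Smyd2 and BC048546 kept their calls without any 1 library. Smyd2 shares 814 exonic bases with Gm37422 on the opposite strand, a gene without counts of its own here. Whether its reads were counted for Smyd2 was not tested.

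The 10 largest falls included genes of the heart muscle and of secreted peptides, together with genes of neither kind. Lrrc10, a leucine-rich repeat gene of cardiac muscle, fell by 2.57 ± 0.20 (SE) on the log2 scale to 6.54 ± 1.56 CPM (SD, n = 2). Adm, the gene of the vasodilator peptide adrenomedullin, fell by 2.54 ± 0.12. Lad1, a basement membrane anchor gene, fell by 3.42 ± 0.20 from 25.3 ± 4.85 CPM (SD, n = 3). The transporter gene Slc12a8 fell by 2.51 ± 0.16, the water channel gene Aqp4 fell by 2.48 ± 0.41 and the synaptic scaffold gene Shank2 fell by 2.60 ± 0.53. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 3.8e-04 for Lad1, 1.6e-03 for Lrrc10 and 2.8e-05 for Adm. The noncoding locus 2210020M01Rik fell by 3.99 ± 0.12. Gm13054 fell by 2.37 ± 0.13, but it shares 532 exonic bases with Nppa on the opposite strand, so its reads and those of Nppa could not be told apart. Aqp4 lost its call without control 2 or mutant 7 (highest adjusted p = 0.12, edgeR), and Shank2 without control 2, control 4, mutant 5 or mutant 7 (highest 0.14).

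**Figure D2:**
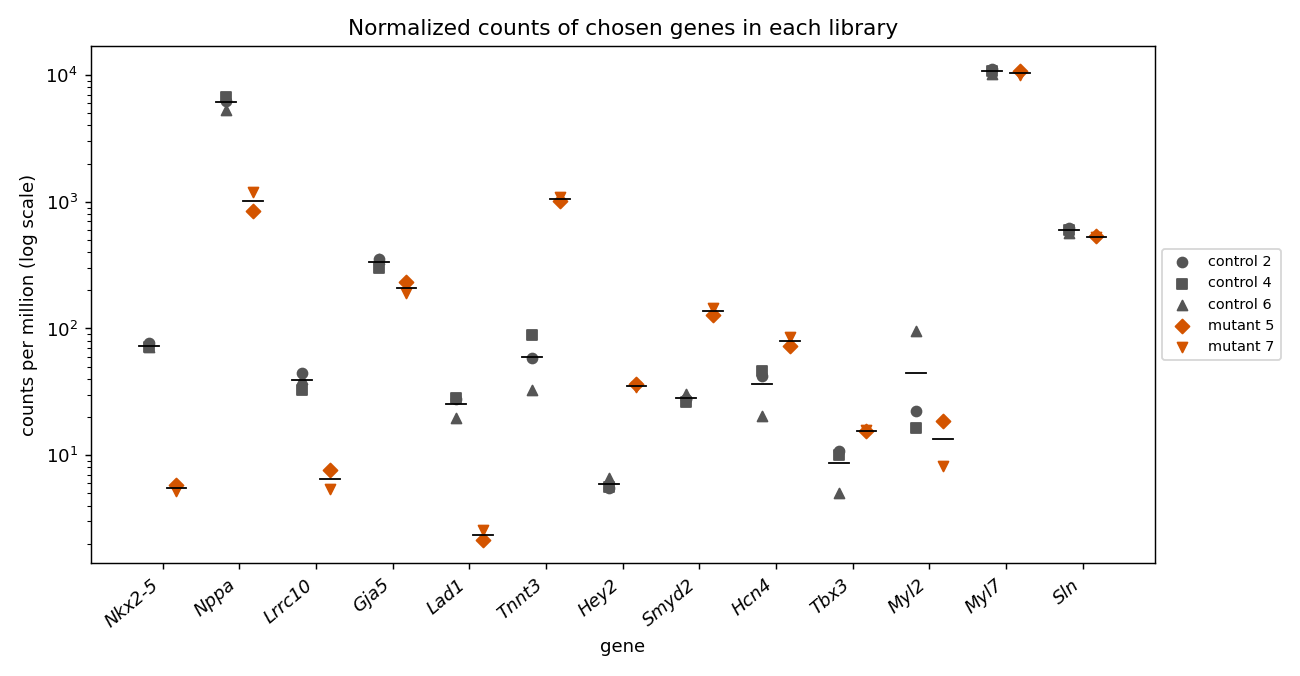
Levels in CPM on a log axis (y) for 13 genes (x) in each of the 5 libraries, with controls in grey, mutants in orange and a black bar for each group mean. Nkx2-5 stands at 71.3 to 76.8 CPM in the controls and at 5.21 to 5.79 CPM in the mutants, while the groups of Myl7 overlap.

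The atrial working myocyte list asked whether the contractile and secretory identity of the atrium changed with Nkx2-5. Of its 20 tested members, 4 fell, 1 rose and 15 did not pass, and the counts adjusted over the list alone were also 4 and 1. Besides Nppa, Pam, an enzyme gene of peptide amidation whose product is abundant in atrial granules, fell by 1.51 ± 0.10 (SE) on the log2 scale, from 3909 ± 367 CPM (SD, n = 3) to 1369 ± 98.8 CPM (SD, n = 2). Gja5, the gene of the atrial gap junction protein connexin 40, fell by 0.68 ± 0.11 (adjusted p = 0.013, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The growth factor gene Bmp10 rose by 0.53 ± 0.10, a call lost without control 4, control 6 or mutant 7 (highest adjusted p = 0.10, edgeR). Myl7, the atrial myosin light chain gene, stood at 10712 ± 399 CPM (SD, n = 3) and 10383 ± 614 CPM (SD, n = 2), and its log2 fold change of -0.05 ± 0.08 did not pass (adjusted p = 0.82, edgeR). As a set the list did not pass camera (median log2 fold change -0.03; adjusted p = 0.18, and 0.81 with an estimated correlation).

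The conduction and pacemaker list asked whether nodal genes changed. Of 25 tested members, 3 rose, 2 fell and 20 did not pass, with 4 and 5 adjusted over the list alone. The calcium sensor gene Vsnl1 rose by 1.13 ± 0.09 (SE) on the log2 scale, while the potassium channel subunit gene Kcne1 fell by 2.00 ± 0.23 and the transcription factor gene Etv1 by 0.82 ± 0.10. Smoc2 rose by 1.66 ± 0.27, a call lost without control 4, mutant 5 or mutant 7 (highest adjusted p = 0.25, edgeR). The remaining rise was that of the pacemaker channel gene Hcn2. Hcn4, also a pacemaker channel gene, stood at 42.1, 45.8 and 20.5 CPM in controls 2, 4 and 6. It stood at 72.8 and 86.3 CPM in mutants 5 and 7. Its log2 fold change of 1.14 ± 0.40 did not pass edgeR's test with Benjamini-Hochberg adjustment (adjusted p = 0.24), and neither did that of the nodal repressor gene Tbx3 (0.86 ± 0.32, adjusted p = 0.22). Control 6 was low for several nodal genes, as it was for some of the largest rises. Shox2, for example, stood at 12.7 CPM there and at 22.9 to 28.5 CPM in the other 4 libraries. Leaving control 6 out gave 4 members higher and 4 lower, and 1 was higher without control 4 or mutant 5. The list did not pass camera (median 0.01, mean -0.00, opposite in sign; adjusted p = 0.71, and 0.88 with an estimated correlation).

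Ventricular myocyte genes were examined as markers of the neighbouring chamber. Of 12 tested members, 2 rose, 1 fell and 9 did not pass, with 2 and 3 adjusted over the list alone. Hey2 rose by 2.59 ± 0.10 (SE) on the log2 scale, and the transcriptional cofactor gene Lbh rose by 0.63 ± 0.08. The cofactor gene Cited1 fell by 0.50 ± 0.09, a call lost without control 2 or control 4 (highest adjusted p = 0.066, edgeR). Myl2, the ventricular myosin light chain gene, stood at 22.3, 16.3 and 95.9 CPM in controls 2, 4 and 6 and at 18.5 and 8.26 CPM in mutants 5 and 7. Its log2 fold change of -1.74 ± 1.17 did not pass edgeR's test with Benjamini-Hochberg adjustment (adjusted p = 0.53). Myl3, another myosin light chain gene of the list, stood at 124, 67.2 and 145 CPM in controls 2, 4 and 6. It stood at 22.3 and 15.4 CPM in mutants 5 and 7, and it was not among the members that passed. Both genes were highest in control 6. With DESeq2, 2 members of the list were called higher and 3 lower. The list did not pass camera (median -0.08; adjusted p = 0.69, and 0.83 with an estimated correlation).

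Channel and gap junction genes changed in both directions. Of 26 tested members, 4 rose, 5 fell and 17 did not pass, with 5 and 10 adjusted over the list alone. Without mutant 7, 2 rose, and without control 2 or control 6, 3 fell. The sodium channel subunit gene Scn4b rose by 3.09 ± 0.37 (SE) on the log2 scale, from a low level of 0.116 ± 0.026 CPM (SD, n = 3) to 1.01 ± 0.14 CPM (SD, n = 2). Kcnip2 rose by 0.86 ± 0.12 and the potassium channel regulator gene Abcc9 by 1.51 ± 0.17. Both lost their calls without mutant 7, with adjusted p = 0.052 and 0.059 in edgeR. Kcne1 and Gja5 were among the falls. The list median was -0.15 and its mean 0.02, and it did not pass camera (adjusted p = 0.60, and 0.81 with an estimated correlation). Of 22 calcium handling genes, 1 fell and 21 did not pass. That gene was the calmodulin kinase gene Camk2d, which fell by 0.35 ± 0.06, a call lost without control 2 or control 6 (highest adjusted p = 0.085, edgeR). The calcium list had a median of 0.02, a mean of -0.04 and a camera adjusted p of 0.66 (0.83 with an estimated correlation).

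Notch signalling and cardiac transcription factors were tested next. Of 32 Notch pathway genes, 3 rose, 2 fell and 27 did not pass, with 4 and 4 adjusted over the list alone. The 3 rises became 1 without control 2, control 4, control 6 or mutant 7 and 8 without mutant 5. The effector genes Hey2 and Hey1 went in opposite directions, Hey2 as above and Hey1 down by 0.60 ± 0.08 (SE) on the log2 scale. Mfng, a glycosyltransferase gene that modifies Notch receptors, rose by 0.87 ± 0.18, a call lost without control 2, control 4, control 6 or mutant 7 (highest adjusted p = 0.10, edgeR). The receptor gene Notch1 stood at 70.2 to 80.1 CPM in the controls, at 74.7 CPM in mutant 5 and at 137 CPM in mutant 7. Its log2 fold change of 0.48 ± 0.28 did not pass edgeR's test with Benjamini-Hochberg adjustment (adjusted p = 0.44), and that of the ligand gene Jag1 was 0.17 ± 0.15 (adjusted p = 0.60). Notch1 shares 1068 exonic bases with a gene on the opposite strand. The Notch list did not pass camera (adjusted p = 0.49, and 0.81 with an estimated correlation). Of 27 cardiac transcription factor genes, 2 rose, 2 fell and 23 did not pass; 1 rose without control 2, control 4 or mutant 7, and 4 fell without mutant 5. Tbx20 rose by 0.62 ± 0.09. Hopx, a homeodomain cofactor gene of the myocardium, fell by 0.84 ± 0.07. Mef2c rose by 0.41 ± 0.08, a call lost without control 2, control 4 or mutant 7 (highest adjusted p = 0.087, edgeR). This list did not pass camera either (adjusted p = 0.60, and 0.81 with an estimated correlation).

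The cell cycle lists asked whether genes of proliferation differed between the groups. All 35 tested G2 and M phase genes had a positive log2 fold change, and 12 of them passed over all tested genes and 30 adjusted over the list alone. The count of 12 was at most 1 without control 2, control 4 or control 6, and 6 when libraries were scaled by their totals. The centromere gene Cenpf rose by 0.63 ± 0.10 (SE) on the log2 scale, the mitotic transcription factor gene Foxm1 by 0.39 ± 0.07, the kinesin gene Kif2c by 0.39 ± 0.07 and the cyclin gene Ccnb1 by 0.33 ± 0.06. Cenpf lost its call without control 4 (adjusted p = 0.052, edgeR). The other 3 lost theirs without control 2, control 4 or control 6, with highest adjusted p = 0.065, 0.067 and 0.072 in edgeR. The list median was 0.27 and camera gave an adjusted p of 4.4e-12, but this was lost with an estimated correlation (adjusted p = 0.62) and with fry (adjusted p = 0.080). Of 34 G1 and S phase genes, 3 rose and 31 did not pass, with 4 adjusted over the list alone; none of the 3 rises was kept without control 2, control 4 or control 6. The cyclin gene Ccnd2 rose by 0.36 ± 0.07, a call lost without control 2, control 4 or control 6 (highest adjusted p = 0.096, edgeR). The median of this list was 0.13, with a camera adjusted p of 6.0e-04 that was lost with an estimated correlation (adjusted p = 0.81) and without mutant 5 (median 0.07, adjusted p = 0.29). Of 16 genes of CDK inhibitors and the retinoblastoma family, only the stress response gene Gadd45g passed, with a rise of 1.16 ± 0.16 that was lost without mutant 7 (adjusted p = 0.072, edgeR). That list had a median of -0.01, a mean of 0.12 and a camera adjusted p of 0.61 (0.81 with an estimated correlation).

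Sarcomere and metabolic genes shifted little in 1 direction as groups. Fry's mixed version gave an adjusted p of 2.2e-05 for sarcomere and 7.9e-05 for glycolysis genes. It gave 7.6e-04 for fatty acid oxidation and 0.0081 for oxidative phosphorylation genes. Such values were not particular to these lists, as the channel list had 7.9e-05 and the atrial list 1.4e-04 by the same test. Of 30 sarcomere genes, 2 rose, 2 fell and 26 did not pass, with 3 and 3 adjusted over the list alone; 1 rose without control 2, control 4 or control 6. Mylk3, the cardiac myosin light chain kinase gene, fell by 1.17 ± 0.10 (SE) on the log2 scale from 321 ± 24.5 CPM (SD, n = 3) to 143 ± 18.2 CPM (SD, n = 2), and the slow troponin gene Tnnt1 fell by 0.89 ± 0.12. The Z disc gene Myoz2 rose by 0.53 ± 0.07. The sarcomere list did not pass camera (median 0.02; adjusted p = 0.48, and 0.81 with an estimated correlation). Among 50 oxidative phosphorylation genes, the muscle form gene Cox8b fell by 0.56 ± 0.08, with 2 further falls and 1 rise (1 fall without control 2 or control 4, and 3 rises without mutant 7), although the list median was 0.08. Camera gave an adjusted p of 0.0099 for this list, lost with an estimated correlation (adjusted p = 0.81), without control 6 (median 0.05, adjusted p = 0.19) and without mutant 5 (adjusted p = 0.25). Among 27 fatty acid oxidation genes, 3 rose and 1 fell, the last being the lipoprotein lipase gene Lpl, which fell by 0.70 ± 0.11. The 3 rises became at most 1 without control 2, control 4 or control 6 and 6 without mutant 7. That list had a camera adjusted p of 0.060 (0.81 with an estimated correlation), which ran from 0.0021 without mutant 7 to 0.63 without mutant 5, where the median turned to -0.01. Among 23 glycolysis genes, 3 rose and 1 fell. Hk1 rose by 0.46 ± 0.07 and Pgam1 by 0.58 ± 0.08, while Aldoc fell by 0.68 ± 0.11. The glycolysis median was 0.10 with a camera adjusted p of 0.042, lost with an estimated correlation (adjusted p = 0.81) and without control 4 (0.079), control 6 (0.19) or mutant 5 (0.35); its median was 0.15 without control 2 and 0.16 without mutant 7. With sex as a covariate the glycolysis call was also lost (adjusted p = 0.081).

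Signalling lists and stress genes held individual changes in both directions. Of 30 BMP and TGF-beta pathway genes, 4 rose and 26 did not pass, with 6 adjusted over the list alone. Tgfb3 rose by 0.46 ± 0.07 (SE) on the log2 scale. The 4 rises became 2 without control 2, control 4 or control 6, 7 without mutant 5 and 1 without mutant 7. The pathway median was 0.09, and 0.19 without mutant 5, with a camera adjusted p of 0.042, lost with an estimated correlation (adjusted p = 0.65) and without control 2 (0.062), control 4 (0.057), mutant 5 (0.061) or mutant 7 (0.36). Of 32 Wnt pathway genes, 2 rose and 3 fell, with 2 and 7 adjusted over the list alone. Without mutant 5, 4 rose, and without control 4 or mutant 7, 1 fell. The 2 rises were the secreted antagonists Sfrp5 and Dkk1, the latter by 2.72 ± 0.45 from 0.072 CPM to 0.487 CPM and lost without mutant 7 (adjusted p = 0.052, edgeR). The inhibitor gene Nkd1 fell by 0.84 ± 0.14, also lost without mutant 7 (adjusted p = 0.059, edgeR). The Wnt list did not pass camera (median -0.18, mean -0.03; adjusted p = 0.10, 0.62 with an estimated correlation, and 0.045 with the stricter filter). Of 21 myocardial stress genes, 3 rose and 3 fell, or 1 fell without control 4 or control 6. Nppb, the gene of B-type natriuretic peptide, fell by 2.13 ± 0.15 from 472 ± 56.1 CPM (SD, n = 3) to 108 ± 18.9 CPM (SD, n = 2). The matrix signalling gene Ctgf rose by 1.07 ± 0.10. The stress list did not pass camera (adjusted p = 0.41, and 0.81 with an estimated correlation). Of 16 immediate early genes, 1 rose and 2 fell. The rise, of Egr2, was lost in each fit without 1 library, that is control 2, control 4, control 6, mutant 5 or mutant 7 (highest adjusted p = 0.11, edgeR), and 2 members rose without control 6. Klf4 fell by 0.91 ± 0.09 and Klf2 by 0.54 ± 0.09. That list had a median of 0.24 and a camera adjusted p of 0.087 (0.81 with an estimated correlation), which ran from 4.1e-04 without control 6 (median 0.49) to 0.65 without mutant 5 (median 0.06).

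Markers of the other cell types of the atrium moved in different directions. All 14 epicardial markers had a negative log2 fold change and 10 passed, with 12 adjusted over the list alone. The keratin gene Krt19 fell by 0.79 ± 0.07 (SE) on the log2 scale, Lrrn4 by 0.74 ± 0.07 and the uroplakin gene Upk3b by 0.79 ± 0.10, from 467 ± 54.1 CPM (SD, n = 3) to 271 ± 6.90 CPM (SD, n = 2). The epicardial median was -0.56 with a camera adjusted p of 1.5e-09. This was lost with an estimated correlation (adjusted p = 0.29), while fry gave an adjusted p of 0.021. Of 18 fibroblast markers, 6 fell, 1 rose and 11 did not pass, with 9 and 1 adjusted over the list alone. The proteoglycan genes Lum and Dcn fell by 0.92 ± 0.09 and 0.80 ± 0.08. The fibroblast median was -0.31 with a camera adjusted p of 5.6e-04, lost with an estimated correlation (adjusted p = 0.62), with fry (adjusted p = 0.13) and without mutant 5 (adjusted p = 0.078).

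Most vascular and leukocyte markers had positive log2 fold changes, but few of them passed. Of 18 endothelial and endocardial markers, 17 had a positive log2 fold change and 2 passed, with 9 adjusted over the list alone. At most 1 passed without control 2, control 4, control 6 or mutant 7, and 7 passed without mutant 5. Eng rose by 0.38 ± 0.07 (SE) on the log2 scale and Tie1 by 0.33 ± 0.08, both lost without control 2, control 4 or control 6, and Tie1 also without mutant 7 (highest adjusted p = 0.11 and 0.17, edgeR). The endothelial median was 0.30, and 0.18 without mutant 7, with a camera adjusted p of 1.2e-04 that was lost with an estimated correlation (adjusted p = 0.62) and with fry (adjusted p = 0.14). All 14 smooth muscle and pericyte markers had a positive log2 fold change and 2 passed, or 5 without mutant 5 and 1 without mutant 7. Acta2, the smooth muscle actin gene, rose by 1.84 ± 0.14 from 411 ± 39.0 CPM (SD, n = 3) to 1469 ± 318 CPM (SD, n = 2), and Abcc9 rose as above. Myh11 stood at 6.51, 9.14 and 2.03 CPM in controls 2, 4 and 6 and at 29.7 and 27.7 CPM in mutants 5 and 7, without passing edgeR's test with Benjamini-Hochberg adjustment (adjusted p = 0.19). The smooth muscle median was 0.57, and 0.37 without mutant 7, with a camera adjusted p of 8.1e-05, lost with an estimated correlation (adjusted p = 0.29) and with fry (adjusted p = 0.062). Of 18 leukocyte markers 3 rose, with 5 adjusted over the list alone, and at most 1 without control 2, control 4, control 6 or mutant 7. The highest of these was S100a8, up by 1.41 ± 0.31 to 1.18 CPM, a call lost without control 2, control 4, mutant 5 or mutant 7 (highest adjusted p = 0.11, edgeR). The leukocyte median was 0.34 with a camera adjusted p of 6.0e-04, lost with an estimated correlation (adjusted p = 0.29), with fry (adjusted p = 0.062) and without mutant 5 (adjusted p = 0.078).

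Of 12 erythroid markers, 2 rose and 1 fell, with 6 and 1 adjusted over the list alone. Hba-a1 rose by 0.48 ± 0.09 (SE) on the log2 scale, but it shares near-identical sequence with Hba-a2, which leaves the value uncertain, and its call was lost without control 2 or control 4 (highest adjusted p = 0.081, edgeR). The 2 rises became 4 without control 6 and at most 1 without control 2, control 4 or mutant 7. The erythroid median was 0.49, but 0.30 without control 4 and 0.10 without mutant 5. Its camera adjusted p of 0.042 was lost with an estimated correlation (adjusted p = 0.81), with fry (adjusted p = 0.33), with sex as a covariate (adjusted p = 0.081) and without control 2 (0.11), control 4 (0.057) or mutant 5 (0.55). None of 18 neuron and Schwann cell markers passed edgeR's test, 4 had an unadjusted p under 0.05, and DESeq2 called 1 higher and 2 lower where limma-voom called 0. Their median was -0.37, and -0.73 without mutant 7, with a camera adjusted p of 0.029, lost with an estimated correlation (adjusted p = 0.81) and without control 2 (0.13), control 4 (0.072) or mutant 5 (0.45). Of 13 skeletal muscle markers, Tnnt3 rose and 2 genes fell. The calcium buffer gene Pvalb fell 3.47-fold, and Actn3 fell by 0.97 ± 0.19, a call lost without control 2, control 4 or mutant 7 (highest adjusted p = 0.084, edgeR). The skeletal list did not pass camera (median -0.12, adjusted p = 0.18, and 0.65 with an estimated correlation). Its median ran from -0.43 to -0.07 when 1 library was left out. Of 6 tested lung, thymus and brown fat markers, only Cidea passed, with a rise of 0.57 ± 0.12 that was lost without control 4, control 6 or mutant 7 (highest adjusted p = 0.10, edgeR). Surfactant genes were near the detection limit, with Sftpc at 0.598 CPM in controls and 0.352 CPM in mutants. That list did not pass camera (median -0.58; adjusted p = 0.62, and 0.81 with an estimated correlation).

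**Figure D3:**
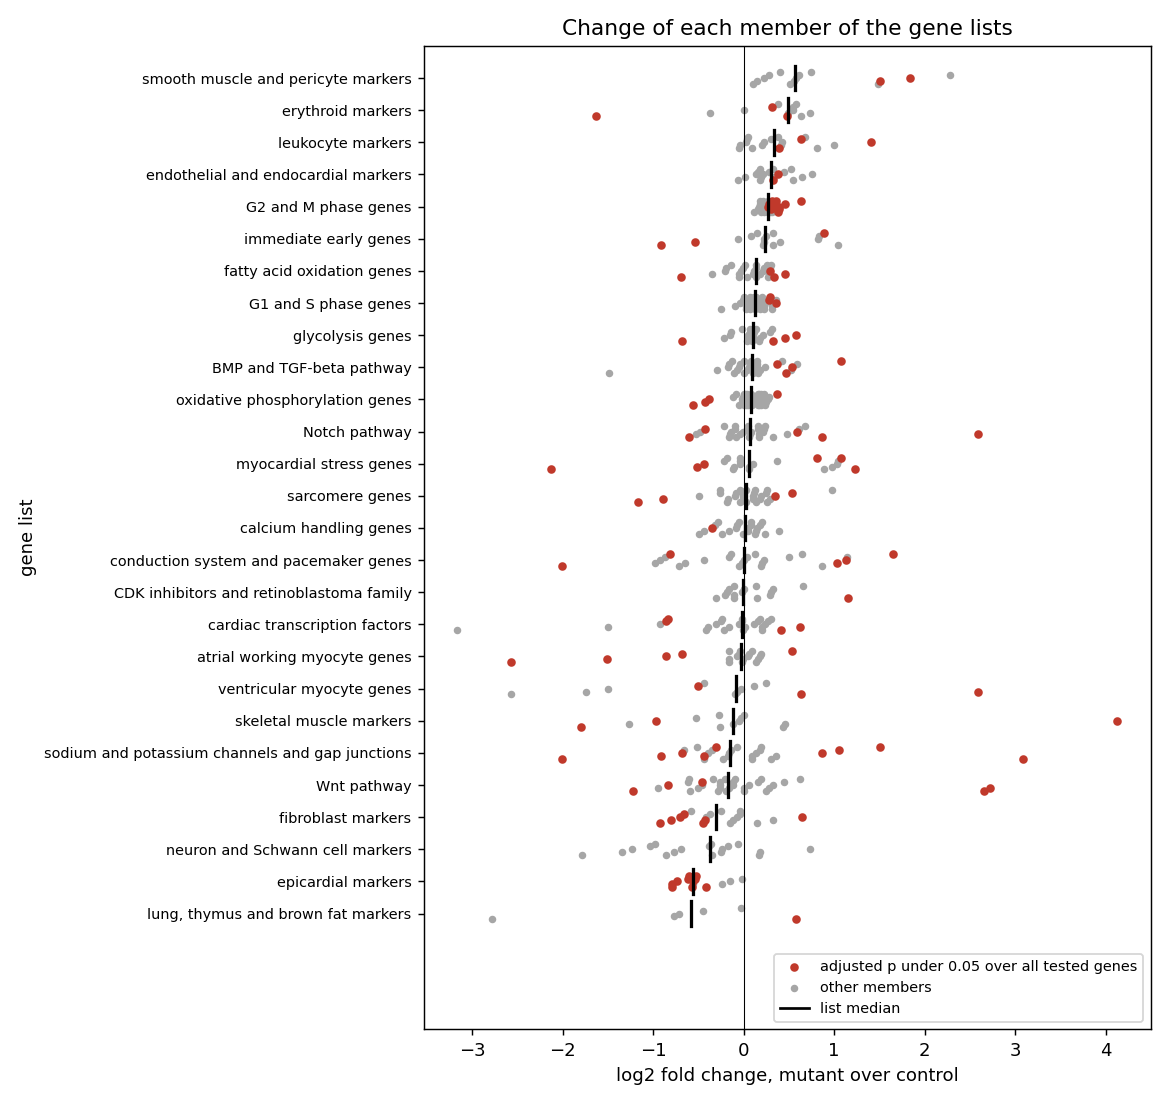
Log2 fold change of mutant over control (x axis) for each tested member of 27 gene lists (y axis), with red points for genes that passed adjusted p under 0.05 over all tested genes in edgeR's test, grey points for the others and a black bar for each list median. All 14 epicardial markers lie below 0, and all 35 G2 and M phase genes lie above it.

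The last comparison set these calls beside the authors' own. The authors' deposited table gave an adjusted p under 0.05 to 1177 genes, 529 higher and 648 lower in mutant atria. Of those genes in the authors' deposited table, 992 were also called here, and all 992 had the same direction in both. A further 185 were called in the authors' deposited table and not here, and 182 were called here and not there. For Nkx2-5 the authors' deposited table gave a log2 ratio of -3.75 and pooled RPKM values of 44.6 in controls and 3.31 in mutants. For Sln the authors' deposited table gave a log2 ratio of -0.19 and an adjusted p of 0.70. Some genes that did not pass here passed in the authors' deposited table, among them Hcn4 (adjusted p = 0.028), Tbx3 (adjusted p = 0.0017) and Myh11 (adjusted p = 8.4e-15). The shorter of the authors' deposited tables held 647 genes with a higher and 695 with a lower value in mutant atria.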

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

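The test of a sex by genotype difference, and the tests below of shared reads, animal background, cell composition, endothelial change and splits of the libraries, were chosen only after the results were seen; the test of sex against animal was written before, and thinning for sequencing depth was added after the data had been seen but before its own result was.

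In a fit with a sex by genotype term, 107 genes had an adjusted p under 0.05 for that term in edgeR's quasi-likelihood test, with 1945 genes at an unadjusted p under 0.05. Only the female controls 2 and 6 form an arm of more than 1 library, so the spread in this fit comes from those 2 libraries and these calls are not taken as shown differences between the sexes. Ifltd1, for example, stood at 69.5, 5.21 and 62.7 CPM in controls 2, 4 and 6 and at 88.0 and 12.9 CPM in mutants 5 and 7. Of the 107 genes, 1 was also called between the genotypes. Among named genes, the male minus female difference was -0.99 for Notch1 and -1.003 for BC048546 on the log2 scale. List medians of this difference with an adjusted camera p under 0.05 were 0.21 for ventricular, 0.14 for sarcomere, 0.20 for fatty acid oxidation, 0.43 for immediate early, -0.19 for endothelial, 0.32 for erythroid and -0.90 for neuron and Schwann cell genes. All 7 were lost with an estimated correlation (camera adjusted p = 0.72, the smallest of any list). With so few libraries per arm that version of camera could hardly pass any list, so the loss says little.

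With only 1 male library per group, the sex by genotype contrast weighs control 4 and mutant 7 against the other 3 libraries. Sex and the single animal therefore cannot be told apart. The contrast also fits sex and genotype, so it is not the plain split of those libraries, which called 5 genes. Reads shared with related sequences may contribute, because pseudogenes and predicted loci made up 23.4% of the 107 genes and 13.3% of the other tested genes (odds ratio 1.98, 95% interval 1.21 to 3.14). A strain background that differs between the animals is a candidate explanation too, because 83 of these genes with coordinates formed 74 pairs within 5 Mb, against a median of 19 in random sets (permutation p = 5e-04, the smallest that 2000 draws can give). Of the 107 genes, 9 are mitochondrial, and the mitochondrial share of counts was 5.89% in control 4 and 7.62% in mutant 7 against 4.81% to 5.15% in the others, so RNA or tissue quality stays open, as does a biological sex difference.

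All 14 epicardial markers had negative log2 fold changes and 10 passed, while 6 of 18 fibroblast markers fell and 1 rose; with an estimated correlation neither list passed camera (adjusted p = 0.29 and 0.62). A larger share of myocytes diluting every other cell type would lower endothelial markers as well, but their median was 0.301 (95% bootstrap interval over genes, taken as independent, 0.185 to 0.414) and 0.18 without mutant 7; that list too was lost with an estimated correlation (adjusted p = 0.62) and with fry (adjusted p = 0.14). Fewer epicardial cells in the mutant tissue may explain the 14 negative values. Lower expression per cell would give the same values and was not tested.

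All 35 G2 and M phase genes had positive log2 fold changes, but 23 did not pass, and the list call was lost with an estimated correlation (adjusted p = 0.62) and with fry (adjusted p = 0.080). The mutant libraries were deeper, and the list median was 0.284 after all libraries were thinned to 58501200 counts, against 0.272 before. Thinning leaves the expected share of each gene in its library unchanged, so this cannot decide whether depth contributed. The endothelial median minus the G2 and M median was 0.029 (95% interval over genes -0.099 to 0.140), so no difference was shown. That interval leaves out the spread between libraries. When 1 library was left out, the endothelial median ran from 0.18 to 0.32 and the G2 and M median from 0.24 to 0.29. Whether a larger endothelial share contributes cannot be told apart from other causes in whole tissue.

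Of the 10 splits of the 5 libraries into 2 and 3, 1 gave as many called genes as the genotypes (1174, the genotypes themselves), and the highest of the others gave 6. The 10 splits are too few for a share under 0.05.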

How the results depend on the processing

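Thinning, the sex by genotype interaction with its estimated correlation and term enrichment were chosen only after the results were seen. Across the alternatives, the results for named genes stayed on the same side of the threshold in 1671 cases, lost a call in 221 and gained one in 46. Gene lists did so in 416, 50 and 6 cases. For limma-voom camera ran on the same log2 CPM as in the main fit, so its list cases could not differ. The sign changed in 3 cases for named genes (Notch1, Jag1 and Myl7, each without mutant 7) and in 17 cases for the medians of 8 lists, among them the Notch list without mutant 7 and the conduction, sarcomere and calcium lists with library totals alone. In 0 of these cases did the result pass its threshold (edgeR's test or camera) on either side.

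DESeq2 called 924 genes higher and 1032 lower, and a threshold of 0.01 left 157 and 234. At that threshold all 391 called genes were shared with the authors' deposited calls, against 992 of 1174 at 0.05. The stricter threshold keeps only the genes with the smallest adjusted p here, so this does not show closer agreement. Leaving out each library gave 203 to 910 genes higher and 306 to 804 lower; without a mutant library the remaining one is assumed to vary like the controls. With library totals alone, 449 genes were higher and 799 lower. The Wnt list passed camera with the filter of at least 1 CPM in 2 libraries (adjusted p = 0.045). The atrial list passed camera with DESeq2's values (median -0.0292, adjusted p = 1.0e-04), against 0.11 to 0.39 by camera without 1 control library. For DESeq2 camera ran on z scores made from its p-values and signs instead of log2 CPM. The tool and the list statistic therefore changed together. The G1 and S phase list (median 0.13) and the G2 and M phase list (median 0.27) no longer passed with an estimated correlation or with fry. Their medians come from edgeR's fold changes and do not depend on the list test. No list passed camera with an estimated correlation. The G1 and S phase median ran from 0.0696 without mutant 5, where its call was lost, to 0.19 without mutant 7. Apart from the smaller library sets and the stricter threshold, the cause was not tested.

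Thinning all libraries to the smallest total gave 534 genes higher and 632 lower. With 2 mutant libraries, small changes were often missed: in simulated counts edgeR recovered 34.3% of the genes changed 1.5-fold. The alternatives for normalized values, a pseudocount and a filter on low values, were not run because counts were analysed.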

Other observations

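Term enrichment was chosen only after the results were seen; the tests of neighbouring genes and of the region around Nkx2-5 were written before.

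Among genes higher in mutant atria, 6 of the 19 tested genes annotated with positive regulation of cardiac muscle cell proliferation were called (Hey2, Nrg1, Tbx20, Bmp10, Mef2c and Ccnb1; 0.661 expected, adjusted p = 0.014, hypergeometric test). The actin cytoskeleton term held 19 of 145 (5.04 expected, adjusted p = 0.0014), among them the smooth muscle marker Acta2; the smooth muscle list had a median log2 fold change of 0.57. Among genes lower in mutant atria, the extracellular matrix term held 27 of 171 (adjusted p = 1.4e-06), among them the fibroblast markers Lum and Dcn, and the basement membrane term 14 of 80 (adjusted p = 0.0027), with Lad1, Col4a3 and Col4a4. Genes of these 2 terms also lay among the higher genes, 13 of 171 and 8 of 80 (adjusted p = 0.23 for each), with Col4a5 and Col4a6 in the latter. In each direction 6 of 2186 terms passed. The others among higher genes were cytoskeleton, microtubule-based movement (12 of 76), microtubule associated complex and blood vessel morphogenesis. Among lower genes, extracellular space had the smallest adjusted p (52 of 495, 6.8e-07, hypergeometric test). Collagen binding, proteinaceous extracellular matrix and axon guidance also passed. In the proliferation term, Bmp10, Mef2c and Ccnb1 lost their calls without some single libraries, as given above.

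Changed genes lay beside each other more often than in shuffled gene orders. Nppb and Nppa are neighbours and both fell, and Alox8 and its neighbour Gucy2e both rose, by 3.26 and 1.86 on the log2 scale. There were 88 adjacent protein-coding pairs called in the same direction, against a median of 43 over 10000 shuffles (permutation p = 1e-04, the smallest the shuffles can give), and 74 against 41 without pairs whose names start alike. Some pairs, such as Dcn with Lum and Krt8 with Krt18, belong to the same list of cell type markers. Shared regulation of neighbouring genes may explain the excess, and so may changed shares of cell types. Neither was tested, nor were reads running between neighbours.

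Passenger DNA flanking the floxed allele might add calls near Nkx2-5. Within 10 Mb of it 17 of 358 tested genes were called, 4.75% against 7.51% of the genes compared elsewhere (odds ratio 0.614, 95% interval 0.352 to 1.002, one-sided Fisher p = 0.985). The genes compared are a subset of all tested genes, of which 6.58% were called. This shows no excess, but a few such calls cannot be told apart from the others.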
